A study of Mus musculus with 11 samples.

How the data were processed

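Total RNA of mouse EpiSCs (129xMF1) was extracted with a Qiagen RNeasy kit and amplified and labelled with biotin by the Illumina TotalPrep-96 protocol, per the labels' protocols. The deposited values are on a log2-like scale and were made with lumi, per the submitters' processing notes, whose version is not given in the sources used here. Whether the authors used a plain log2 or lumi's variance-stabilizing transformation is not given in the sources used here; if it was the latter, log2 changes of dim features understate the change. The sorted deposited log2 values of the 11 arrays differed by at most 0.00116, so the arrays had been quantile-normalized, and total differences in RNA amount between groups are no longer in the values. The deposited table held 15718 probes and no detection p-values, so signal above background could not be set per probe.

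Probes were named through a table that pairs them with GEO's platform annotation: 13711 probes had 1 gene symbol, 5 had several and 2002 were not listed with one and are unnamed here. Symbols were checked by gene number against a RefSeq table (its assembly was used for names only), which changed 0 symbols, and 18 listed probes had no match there. For the 9201 distinct symbols the probe with the highest mean over all arrays was kept, and the 2007 probes without a single symbol were kept as features of their own, which gave 11208 features. Probes of one gene can differ in the size of their change: the 2 probes of Slc30a3 gave 3.23 and 0.29 after G-CSF in GY118F EpiSCs. No filter on dim features was applied.

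Samples were grouped by transgene and treatment from the labels. The stimulated GY118F arrays carry replicate numbers 2 and 3 here, from their source names and the series' design, whereas their titles number them 1 and 2. The source names of the stimulated control arrays all give replicate 1, so these carry the numbers of their titles. All 11 arrays in 4 groups were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a replicate block, and each contrast was tested two-sided with Benjamini-Hochberg adjustment over all features at a threshold of 0.05. The contrasts were G-CSF against unstimulated in each line, the difference between these, and GY118F against control without G-CSF. The contrast of the lines with G-CSF was added after seeing the data. A fold change is the power of 2 of the difference of mean values.

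A total of 22 gene lists were fixed before the data were examined, 21 of which had at least 3 measured members and were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast) and again with an estimated correlation; 1 tested list is not reported here, and counts of lists include it. Markers of fibroblasts, haematopoietic cells, trophoblast, endoderm and neural progenitors were among them. The genes named are, per contrast, the 12 largest rises and the 12 largest falls among called features with 1 symbol and no overlap between the arrays of the groups, leaving out provisional symbols, together with list members and 8 genes fixed beforehand. Genes of the study's stated criterion are named by the size of their rise.

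The fit was tested on simulated data with the features' own means and spread. Of 50 features changed 1.4-fold, 49 were recovered for G-CSF in GY118F EpiSCs, 50 for G-CSF in control EpiSCs, 41 for the difference of G-CSF effects and 50 for GY118F against control without G-CSF, each among 11208 features. At 1.2-fold, 22, 36, 8 and 28 of 50 were recovered in the same order. False calls numbered 6, 8, 10 and 12 in that order. The values were drawn independently for each feature with equal spread in all groups. Far fewer features were changed than were called in the data, so recovery in the data may differ.

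The alternatives were a replicate block with either numbering, a fit of only the groups compared, all probes as features, leaving out the dimmer 50 percent of features, a second quantile normalization, a floor at the 25th percentile, eBayes with trend and robust, array weights, a threshold of 0.01, a fold threshold of 1.4, unadjusted p in the study's criterion and leaving out each array in turn.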

Results

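Gene expression was measured on 11 Illumina mouse arrays in epiblast stem cells (EpiSCs), pluripotent cells that are cultured with Activin and Fgf and resemble the postimplantation epiblast. One EpiSC line carried GY118F, a chimeric receptor that joins the ligand-binding part of the G-CSF receptor to the signalling part of gp130. A tyrosine that recruits Shp2 is replaced in this receptor, and G-CSF then activates the transcription factor STAT3 through it. Unstimulated GY118F EpiSCs (n = 3), GY118F EpiSCs given G-CSF for 3 hours (n = 2), unstimulated control EpiSCs (n = 3) and control EpiSCs given G-CSF for 3 hours (n = 3) were compared. Values are on a log2-like scale from 7.11 to 15.22, with a median of 8.16, and a difference of values is given as a log2 change. Arrays of one group correlated at r = 0.994 to 0.998 across features, and arrays of different groups at r = 0.960 to 0.982; features are not independent replicates. The number of arrays limits the precision, and nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

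The first comparison asked what G-CSF changed in GY118F EpiSCs. Socs3, the feedback inhibitor that STAT3 induces, rose by 3.00 ± 0.05 (SE) on the log2 scale, from 8.96 ± 0.02 (SD, n = 3) to 11.96 ± 0.04 (SD, n = 2), with a limma Benjamini-Hochberg adjusted p of 5.09e-13. Stat3 itself rose by 2.04 ± 0.09 (SE), the Krüppel-like factor Klf5 by 2.12 ± 0.08 (SE) and the transcription factor Tfap2c by 1.99 ± 0.06 (SE). The zinc transporter Slc30a3 rose by 3.23 ± 0.06 (SE), the cornified envelope gene Lor by 2.74 ± 0.07 (SE) and the WNT-responsive factor Sp5 by 2.19 ± 0.12 (SE). Lefty1, a secreted Nodal antagonist, rose by 3.00 ± 0.72 (SE) with a limma Benjamini-Hochberg adjusted p of 0.00524. The GTPases Gbp2b and Gbp2 rose by 2.26 and 1.94, the receptor Cd40 by 2.20 and the Frizzled receptor Fzd10 by 1.81. The largest falls were in Chac1 (-3.99 ± 0.06, SE), a glutathione-degrading enzyme of the integrated stress response, and in Trib3 (-3.09 ± 0.08, SE). Ddit4 (-2.20), Vldlr (-2.10), Rgcc (-1.85), Hspb6 (-1.78), Mthfd2 (-1.72), Txnip (-1.71), Otub2 (-1.64), Gpt2 (-1.56), Stc2 (-1.52) and Ddit3 (-1.41) also fell.

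Among gene lists fixed beforehand, 11 of the 15 measured STAT3 feedback and early targets rose and 1 fell, and the same counts held when adjusted over the list alone. Socs2 rose by 1.56, Junb by 1.48 and Icam1 by 0.87, while Cebpd fell by 0.54. This list moved up against other genes in limma's camera test with a Benjamini-Hochberg adjusted p of 7.08e-07. All 15 measured glycolysis and hypoxia genes fell, Egln3 by 1.13, Vegfa by 1.13 and Pfkl by 1.00 (camera adjusted p = 4.18e-09). Of 13 FGF and ERK feedback targets, 11 rose, Dusp5 by 1.39 and Phlda1 by 0.92 (camera adjusted p = 6.30e-06). These lists were the 3 of the 11 called by camera that held with an estimated correlation, at adjusted p = 0.0144 for the STAT3 list, 0.0467 for glycolysis and hypoxia and 0.0467 for FGF and ERK feedback.

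Primitive streak and mesendoderm genes rose in 7 of 11 cases, with Fgf8 at 1.49 and Eomes at 0.80 (camera adjusted p = 0.000705, adjusted p = 0.147 with an estimated correlation). WNT targets rose in 6 of 7 cases, with Tcf7l1 at 0.68, and Wnt8a fell by 0.40 (camera adjusted p = 0.00304, adjusted p = 0.0538 with an estimated correlation). Among Activin and Nodal targets 6 of 10 rose, including Nodal by 1.65 and Tdgf1 by 1.24, and Foxh1 fell by 0.21 (camera adjusted p = 0.0127, adjusted p = 0.166 with an estimated correlation). Naive pluripotency genes rose in 4 of 9 cases, led by Klf5, with Klf2 at 0.43 and Gbx2 at 0.89, and Fbxo15 fell by 0.25 (camera adjusted p = 0.0176, adjusted p = 0.0904 with an estimated correlation). The trophoblast list rose in 3 of 5 cases (camera adjusted p = 0.0228, adjusted p = 0.147 with an estimated correlation) through Tfap2c, Cdx2 and Bmp4, while the keratins Krt8 and Krt7 stood at 0.07 and -0.04 without a call. General pluripotency genes rose in 5 of 12 cases (camera adjusted p = 0.0381, adjusted p = 0.166 with an estimated correlation), including Trim71 by 0.57 and Pou5f1 by 0.29. Immediate early genes were higher in 6 of 12 cases and lower in 4, with Egr3 at 1.74 and Fos at 1.34 (camera adjusted p = 0.0408, adjusted p = 0.166 with an estimated correlation). Without unstimulated GY118F replicate 2 or 3 the immediate early list was not called (camera adjusted p = 0.0602 and 0.0892), and without GY118F G-CSF replicate 3 neither general pluripotency (camera adjusted p = 0.194) nor Pou5f1 (limma adjusted p = 0.168) was. Fgf5 rose by 0.60 and Il6st, which encodes gp130, by 0.21, a call lost without either stimulated GY118F array (limma adjusted p = 0.0511 and 0.0605), and Nanog stood at 0.01 ± 0.17 (SE) without a call.

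Over 11208 features, 2000 were higher and 2456 lower after G-CSF in GY118F EpiSCs (limma, Benjamini-Hochberg adjusted p under 0.05), and 468 and 472 of these changed over 1.4-fold. Csf3r, which encodes the G-CSF receptor, and Klf4 were not analysed here because no measured feature carried their symbols. Il6st was measured but lay near the floor. With values under the 25th percentile set to it, the Il6st change after G-CSF was 0.03 in GY118F and 0 in control EpiSCs. Its values therefore tell little in any of the comparisons.

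The second comparison asked what G-CSF changed in EpiSCs without the GY118F receptor. Socs3 was lower by 0.17 (-0.17 ± 0.04, SE; limma Benjamini-Hochberg adjusted p = 0.00735) and Stat3 stood at -0.17 ± 0.08 (SE) without a call. Stat3 was called lower in a fit of the control arrays alone (limma adjusted p = 0.0318), with array weights (0.0198) and without either stimulated GY118F array (0.0249). The Activin antagonist Fst rose by 2.40 ± 0.09 (SE), and the homeobox gene Gbx2 rose by 2.28 ± 0.08 (SE). Lor (2.22), Fjx1 (2.12), Slc46a3 (2.02), Slc30a3 (1.90), Sp5 (1.87), the secreted ligand Wnt8a (1.86), the streak gene Evx1 (1.85), Nt5e (1.68), Rerg (1.55) and Sall3 (1.48) also rose. The largest falls were in Chac1 (-4.96 ± 0.06, SE), Trib3 (-3.64 ± 0.07, SE) and the matricellular gene Ccn2 (-2.52 ± 0.12, SE). Herpud1 (-2.31), Ddit4 (-2.27), Vldlr (-2.26), Nupr1 (-2.10), Hspb6 (-1.86), Otub2 (-1.86), Gpt2 (-1.72), Txnip (-1.69) and the amino acid transporter Slc1a4 (-1.55) fell too.

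Of the 15 STAT3 feedback and early targets, 2 rose and 6 fell in control EpiSCs, and the list as a whole was not called by camera (adjusted p = 0.408). Socs2 rose by 0.79 and Gadd45g by 0.31, while Cebpb fell by 1.06. Glycolysis and hypoxia genes fell in 14 of 15 cases, with Vegfa at -1.49 (camera adjusted p = 1.51e-08, adjusted p = 0.0697 with an estimated correlation). In the heat shock and unfolded protein stress list 7 of 12 fell and 3 rose (camera adjusted p = 0.00392, adjusted p = 0.0697 with an estimated correlation). The members that fell included Chac1, Trib3, Ddit3 (-1.52), Atf4 (-1.24) and Asns (-0.95), genes of the ATF4 branch of the stress response, whereas the chaperone genes Hsph1 (0.52), Dnajb1 (0.30) and Hspa8 (0.29) rose. WNT targets rose in 5 of 7 cases (camera adjusted p = 0.000258, adjusted p = 0.0697 with an estimated correlation), and Axin2 rose by 0.57. FGF and ERK feedback targets rose in 8 of 13 cases, with Etv4 at 0.74 (camera adjusted p = 0.000392, adjusted p = 0.0697 with an estimated correlation). Primitive streak and mesendoderm genes rose in 6 of 11 cases, with Eomes at 1.39 and Cdx2 at 1.23 (camera adjusted p = 0.00123, adjusted p = 0.166 with an estimated correlation). General pluripotency genes rose in 9 of 12 cases, with Lin28a at 0.51 and Sox2 at 0.45 (camera adjusted p = 0.00213, adjusted p = 0.0697 with an estimated correlation). The HOX list rose in 3 of 3 cases, with Hoxb2 at 0.75 (camera adjusted p = 0.00788, adjusted p = 0.111 with an estimated correlation). The p53 and apoptosis list rose in 6 of 11 cases, with Cdkn1a at 0.86, and Bbc3 fell by 1.08 (camera adjusted p = 0.0350, adjusted p = 0.324 with an estimated correlation). None of the 9 lists called in control EpiSCs held with an estimated correlation. The naive pluripotency list, not called there (camera adjusted p = 0.174), had 4 of 9 members higher and 1 lower. Pou5f1 rose by 0.24, a call lost without any of 4 single control arrays (limma adjusted p up to 0.107), and Fgf5 by 0.38, a call lost without control unstimulated replicate 3 (limma adjusted p = 0.0714). The p53 list was not called without control unstimulated replicate 2 (camera adjusted p = 0.0538). Nanog (-0.33 ± 0.15, SE) and Il6st (0.12 ± 0.05, SE) were not called, but a second Nanog probe fell by 0.64 with a call. Nanog was called in a fit of the control arrays alone (limma adjusted p = 0.0291), with array weights (0.0489) and without unstimulated GY118F replicate 3 (0.0219), and Il6st with array weights (0.0369).

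In control EpiSCs 2187 features were higher and 2536 lower after G-CSF (limma, Benjamini-Hochberg adjusted p under 0.05). The 2 comparisons share no array, but both use the same estimate of each feature's spread. Their calls are therefore not independent, and the counts for independent lists below are a reference and not a test. Of the 2000 features higher in GY118F EpiSCs, 1382 (69.1%) were also higher in control EpiSCs, against 390.3 for independent lists. Of the 2456 lower ones, 1742 (70.9%) were also lower in control EpiSCs, against 555.7 for independent lists. Only 55 features rose in GY118F and fell in control EpiSCs, and 31 did the reverse, against 452.5 and 479.2 for independent lists. Across the 11208 features the log2 changes of the 2 lines correlated at Pearson's r = 0.754 and Spearman's rho = 0.757. The labels describe no culture handled alongside the stimulated ones without G-CSF.

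**Figure D1:**
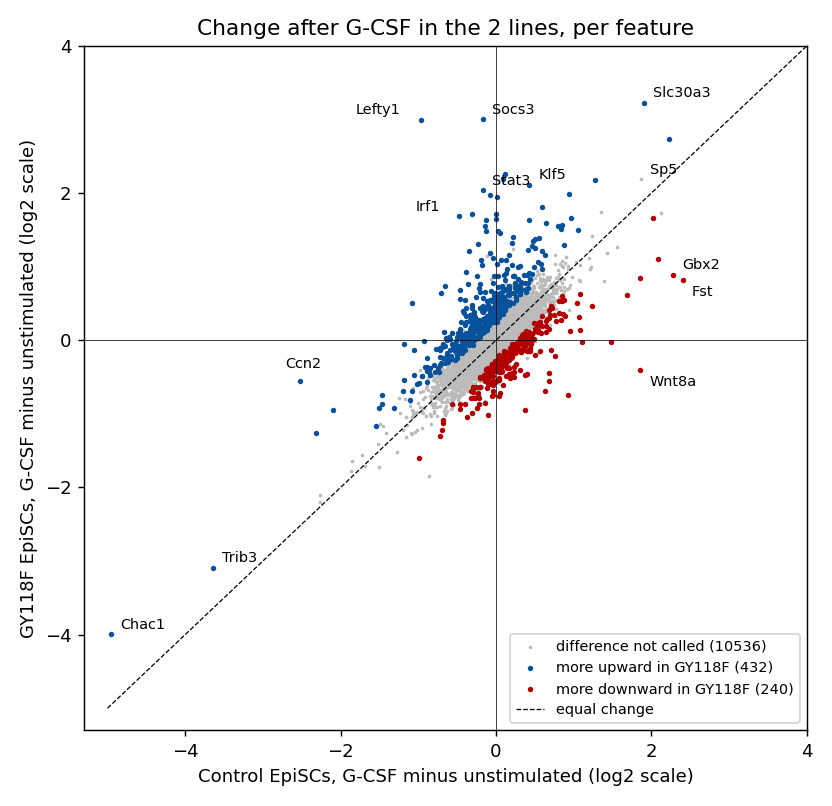
Log2 change after 3 hours of G-CSF in control EpiSCs (x axis) and in GY118F EpiSCs (y axis), 1 point per feature, with the 432 features called more upward in GY118F EpiSCs in blue, the 240 called more downward in red and the line of equal change dashed. Socs3 lies at -0.17 and 3.00, while Chac1 lies at -4.96 and -3.99.

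The third comparison asked which changes after G-CSF differed between the lines. The change in Socs3 was larger in GY118F EpiSCs by 3.18 ± 0.07 (SE; limma Benjamini-Hochberg adjusted p = 1.96e-11), in Stat3 by 2.21 ± 0.12 (SE), in Klf5 by 1.69 ± 0.10 (SE) and in Junb by 1.61 ± 0.07 (SE). The neurotrophin receptor Ngfr (1.72), the transcription factor Irf1 (2.17), Gbp2b (2.15), Cd40 (2.10), Gbp2 (1.93) and Ccn2 (1.97) also had a more upward change in GY118F EpiSCs, in Ccn2 as a smaller fall (-0.56 against -2.52). Lefty1 had a difference of 3.97 ± 0.97 (SE; limma Benjamini-Hochberg adjusted p = 0.0295) and Nodal, the ligand it antagonizes, of 1.64 ± 0.36 (SE; limma Benjamini-Hochberg adjusted p = 0.0180). Differences in the other direction were led by Wnt8a (-2.26 ± 0.09, SE), Sox9 (-1.67), Fst (-1.58), Sall3 (-1.51) and Gbx2 (-1.39), followed by Irx3 (-1.31), Rtl8a (-1.24), Plpp3 (-1.13), Fgfr2 (-1.12), Nt5e (-1.07), Meis2 (-0.98) and, between these, Evx1. Gbx2, Sox9 and Wnt8a were higher in unstimulated GY118F than in unstimulated control EpiSCs, as given below. Ccn2 was lower there (-2.06) and did not differ by a call between the stimulated lines (-0.09). Whether the level before G-CSF accounts for a more downward change or a smaller fall was not tested. Il6st (0.10), Nanog (0.34), Pou5f1 (0.05) and Fgf5 (0.23) were not called, but without unstimulated GY118F replicate 3 the Fgf5 difference was 0.40 and called (limma Benjamini-Hochberg adjusted p = 0.0140).

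Unstimulated GY118F replicate 3 stood apart in Lefty1, at 11.34 against 7.93 and 7.97 in replicates 1 and 2, and in Nodal, at 9.07 against 7.86 and 7.75. The Lefty1 difference between lines lost its call when any of 9 single arrays was left out (limma Benjamini-Hochberg adjusted p up to 0.0863), and without unstimulated GY118F replicate 3 it was 5.09 (limma Benjamini-Hochberg adjusted p = 2.36e-10). The Nodal difference lost its call without either stimulated GY118F array (limma adjusted p = 0.0606 and 0.0573). Under a floor at the 25th percentile (limma adjusted p = 0.127 for Lefty1, 0.0927 for Nodal) and under trend and robust moderation (0.147 and 0.101) both calls were lost.

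**Figure D2:**
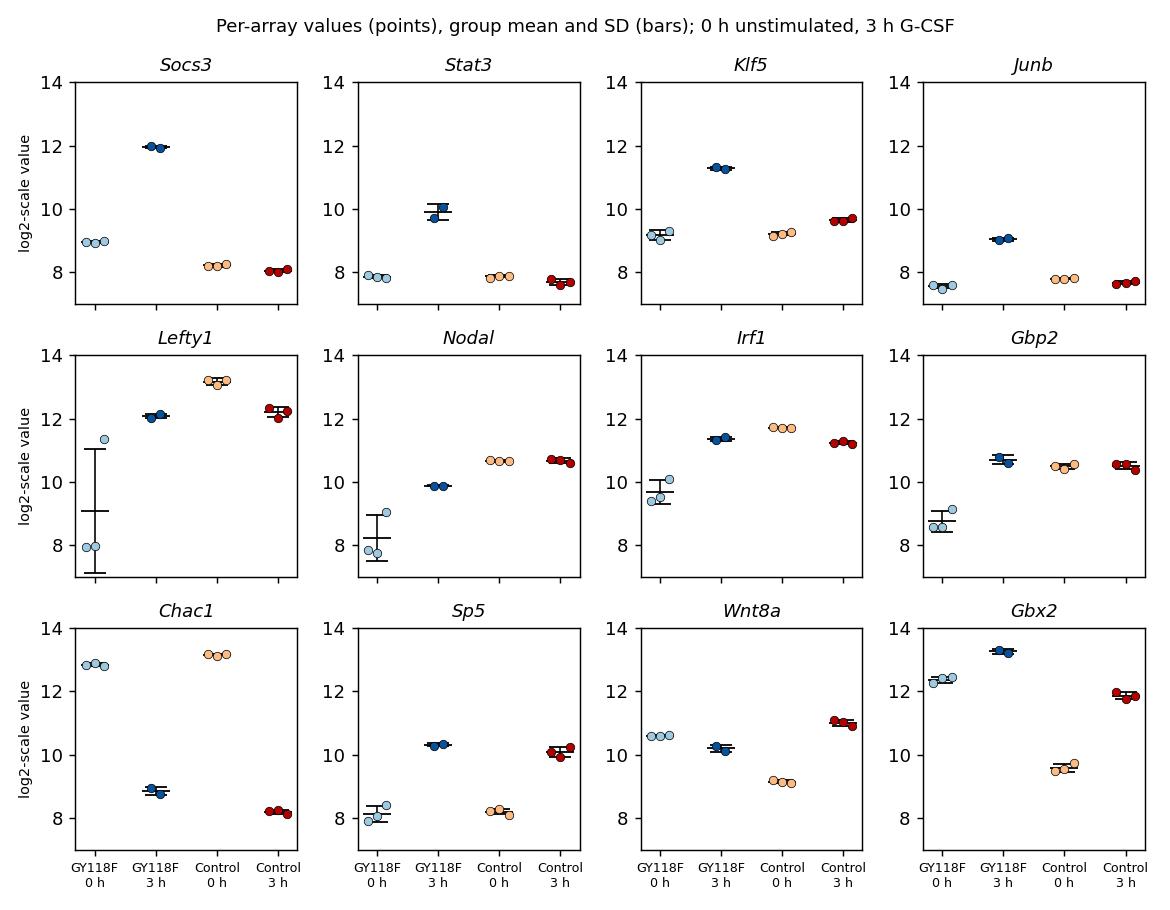
Log2-scale values of 12 genes on each array (points), with the group mean and SD (bars), in unstimulated EpiSCs (0 h) and after 3 hours of G-CSF (3 h). Socs3 reached 11.96 in stimulated GY118F EpiSCs and 8.06 in stimulated control EpiSCs, and Lefty1 spread from 7.93 to 11.34 over the 3 unstimulated GY118F arrays.

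The STAT3 list had a more upward change in GY118F EpiSCs, with 10 of 15 members called in that direction and none in the other, or 13 adjusted over the list alone (camera adjusted p = 6.64e-21, adjusted p = 0.000353 with an estimated correlation). Immediate early genes had 6 of 12 more upward and Egr2 more downward, with Zfp36 at 1.29 and Fos at 0.87 (camera adjusted p = 3.19e-08, adjusted p = 0.0101 with an estimated correlation). Activin and Nodal targets had 5 of 10 more upward, including Fgf8 at 1.46 and Lefty2 at 0.74, and Foxh1 more downward (camera adjusted p = 8.67e-06, adjusted p = 0.0468 with an estimated correlation). The stress list had 4 of 12 more upward, namely Herpud1 (1.05), Xbp1 (0.98), Chac1 (0.96) and Trib3 (0.55), of which Xbp1 rose and the others fell less in GY118F EpiSCs (camera adjusted p = 9.28e-05, adjusted p = 0.0227 with an estimated correlation). The cell cycle list was shifted down with Plk1 (-0.38) as its single called member of 15 (camera adjusted p = 0.00380, adjusted p = 0.0426 with an estimated correlation). The trophoblast list was shifted up with Tfap2c (1.05), Bmp4 (0.62) and Krt8 (0.50) more upward and Cdx2 (-0.77) more downward, and this call was lost with an estimated correlation (camera adjusted p = 0.00516, adjusted p = 0.0736 with an estimated correlation). Glycolysis and hypoxia genes had a mean difference of -0.06 and were not called (camera adjusted p = 0.341). Nor were the lists of naive pluripotency (camera adjusted p = 0.298), general pluripotency (0.265), primitive streak and mesendoderm (0.275), FGF and ERK feedback (0.207) and WNT targets (0.985).

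In all, 432 features had a more upward and 240 a more downward change in GY118F EpiSCs (limma, Benjamini-Hochberg adjusted p under 0.05). Of the 432, 155 rose in GY118F EpiSCs without a call in control EpiSCs, 98 fell in control EpiSCs without a call in GY118F EpiSCs, 72 rose in both lines, 52 fell in both and 55 rose in GY118F and fell in control EpiSCs. Stimulated GY118F EpiSCs were called higher than stimulated control EpiSCs in 258 of the 432 features, lower in 57 and neither in 117, a comparison chosen after seeing the data. Socs3 exceeded stimulated control EpiSCs by 3.91 and Stat3 by 2.20, whereas Lefty1 (-0.11 ± 0.72, SE), Irf1 (0.13 ± 0.15, SE) and Gbp2 (0.19 ± 0.14, SE) did not differ by a call. The count of 432 was 278 without GY118F G-CSF replicate 2, which leaves a single array in that group whose spread is then taken from the other groups. The count of 240 was 151 without unstimulated GY118F replicate 2 and 159 without unstimulated control replicate 2.

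**Figure D3:**
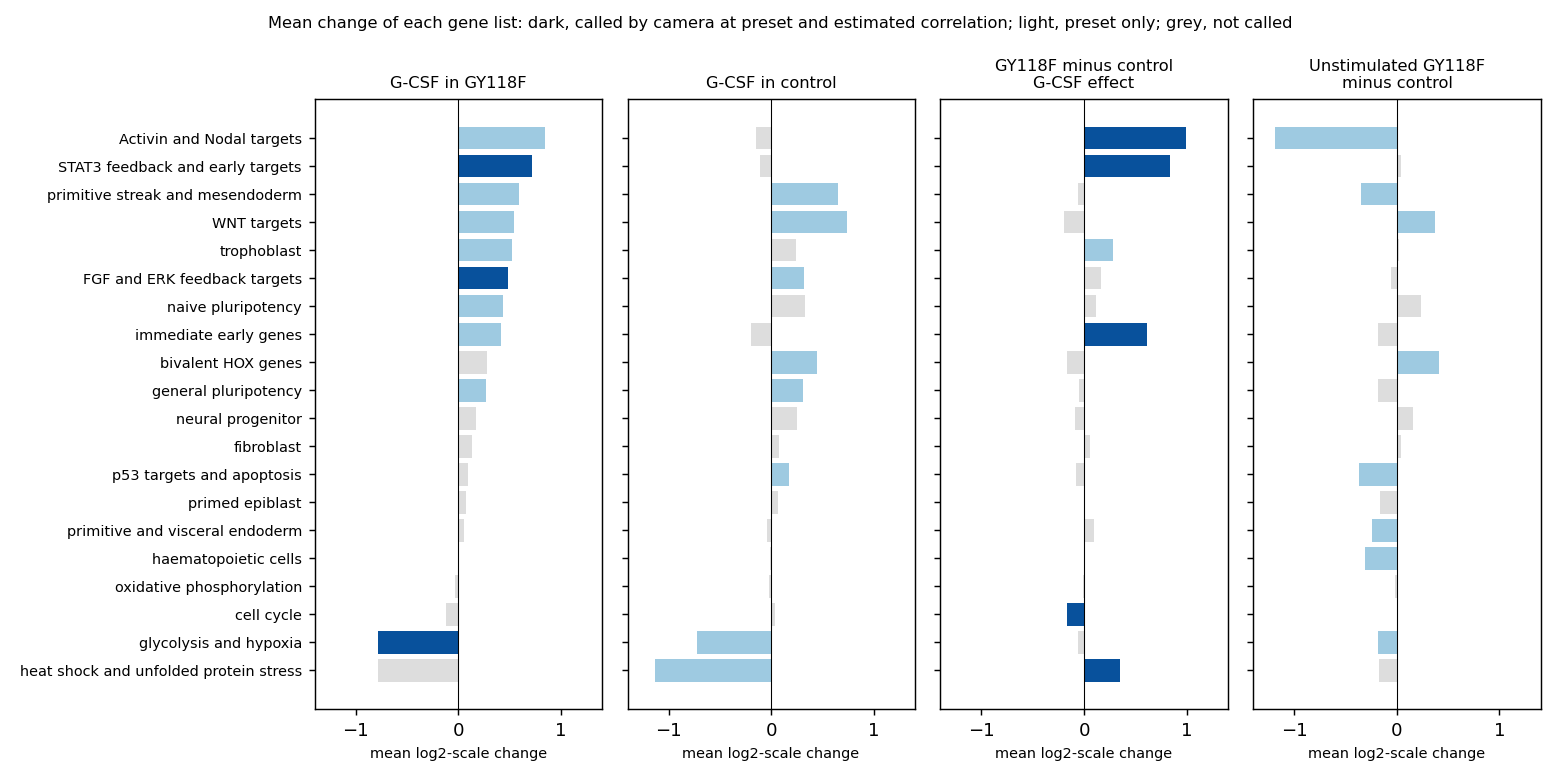
Mean log2 change of 20 tested gene lists (bars) for G-CSF in GY118F EpiSCs, G-CSF in control EpiSCs, the difference between them and unstimulated GY118F minus control EpiSCs, in dark blue where called by camera with both preset and estimated correlation, in light blue with the preset alone and in grey where not called. The STAT3 list stands at 0.72, -0.11, 0.84 and 0.04.

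The study defined genes of interest as those that rose over 1.4-fold after G-CSF in GY118F EpiSCs at a p threshold of 0.01 and did not change significantly in the control. Applied to adjusted p from limma, this rule took 120 features, of which 99 carried 1 gene symbol. Lefty1, Gbp2b, Cd40, Stat3, Gbp2, Ngfr and Nodal had the largest rises of the features with a symbol, from 3.00 to 1.65. The 120 did not include Socs3, whose fall of -0.17 in control EpiSCs was past the threshold of 0.01. A difference between the lines was called for 92 of the 120, and 22 of the 120 were called higher in control EpiSCs at the threshold of 0.05. Before the control criterion the rule took 456 features. With unadjusted p it took 106 features, 84 of them with a called difference.

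The fourth comparison asked how the 2 lines differed before G-CSF. Unstimulated GY118F EpiSCs had less of the Activin and Nodal genes Lefty1 (-4.08 ± 0.64, SE; limma Benjamini-Hochberg adjusted p = 0.000314) and Nodal (-2.44 ± 0.24, SE), less of the epiblast genes Otx2 (-2.09 ± 0.07, SE) and Fgf5 (-1.41 ± 0.11, SE), and less Nanog (-0.90) and Pou5f1 (-0.74). They also had less Ifitm3 (-3.58 ± 0.06, SE), Psmb8 (-2.05), Irf1 (-2.04) and Ifitm1 (-1.85), and less Plod2 (-3.21), Erdr1 (-3.05), Xist (-2.37), Ccn2 (-2.06) and Abcc4 (-1.93). They had more Xlr4a (3.94 ± 0.05, SE), Emb (3.41), Ptn (3.27), Igfbp5 (2.92), Gbx2 (2.78), Crabp1 (2.33), Sox9 (2.18), Gadd45g (2.06), Mfap2 (2.01), Sox21 (2.00), Gdnf (1.95) and Epdr1 (1.92). Socs3 was higher by 0.73 ± 0.04 (SE), while Stat3 (-0.01 ± 0.08, SE) and Il6st (0.08 ± 0.05, SE) were not called.

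Activin and Nodal targets were lower in 8 of 10 cases in unstimulated GY118F EpiSCs, including Fgf8 at -1.66 and Lefty2 at -0.94 (camera adjusted p = 9.46e-05, adjusted p = 0.0946 with an estimated correlation). The p53 and apoptosis list was lower in 8 of 11 cases, with Trp53inp1 at -0.65 (camera adjusted p = 0.000160, adjusted p = 0.112 with an estimated correlation). Primitive streak and mesendoderm genes were lower in 7 of 11 cases, with Gsc at -0.84 (camera adjusted p = 0.00542, adjusted p = 0.236 with an estimated correlation). The list of haematopoietic cell markers was lower in 3 of 5 cases, led by Tal1 at -0.63 (camera adjusted p = 0.00628, adjusted p = 0.0946 with an estimated correlation), and that of primitive and visceral endoderm in 4 of 8, led by Foxq1 at -0.70 (camera adjusted p = 0.00892, adjusted p = 0.0946 with an estimated correlation). Glycolysis and hypoxia genes were lower in 6 of 15 cases, with Pfkp at -0.73 (camera adjusted p = 0.0366, adjusted p = 0.398 with an estimated correlation), a call lost without unstimulated replicate 1 of either line (camera adjusted p = 0.100 and 0.0582). WNT targets were higher in 4 of 7 cases, with Wnt8a at 1.45 and Axin2 at 0.79 (camera adjusted p = 0.0131, adjusted p = 0.0946 with an estimated correlation), and the HOX list in 2 of 3, with Hoxa2 at 0.64 (camera adjusted p = 0.0131, adjusted p = 0.143 with an estimated correlation). The primed epiblast list was not called (camera adjusted p = 0.452), with 2 members higher and 5 lower of 15 and a median of 0.05. General pluripotency was not called either (camera adjusted p = 0.236), with 1 member higher and 5 lower of 12. The STAT3 list had a mean difference of 0.04 and a median of -0.06, with 2 members higher and 5 lower of 15. Camera, which ranked the STAT3 list downward, did not call it (adjusted p = 0.452). Without G-CSF 1873 features were higher and 1850 lower in GY118F than in control EpiSCs (limma, Benjamini-Hochberg adjusted p under 0.05). One line per genotype was analysed, so the transgene and other differences between the lines cannot be told apart.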

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

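The tests of STAT3 activity and of handling in control EpiSCs, the contrast of the stimulated lines and the test on held-out arrays were chosen after the results were seen. A difference of G-CSF effects between the lines was called by limma for 432 features more upward and 240 more downward in GY118F EpiSCs. Among lists, the mean difference was 0.84 for STAT3 feedback and early targets, 1.00 for Activin and Nodal targets, 0.61 for immediate early genes, 0.28 for trophoblast (not called with an estimated correlation), 0.35 for heat shock and unfolded protein stress and -0.16 for the cell cycle. Among the named genes, Socs3 (a difference of 3.18) and Irf1 (2.17) rose in GY118F and fell in control EpiSCs, and Wnt8a (-2.26), Sox9 (-1.67), Irx3 (-1.31), Rtl8a (-1.24) and Plpp3 (-1.13) fell in GY118F and rose in control EpiSCs.

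Most features called after G-CSF in GY118F EpiSCs moved the same way in control EpiSCs, which lack the receptor. STAT3 activation by G-CSF in control EpiSCs is argued against by Socs3, which stood at -0.17 there against 3.00 in GY118F EpiSCs, and by the STAT3 list, which was not called. Handling, medium renewal or an array batch shared by all stimulated cultures may be the source: the stress list fell in control EpiSCs by a mean of 1.14 (-1.14), with a median of -0.58 and 3 of 12 members higher, and stood at -0.79 in GY118F EpiSCs without a call (-0.80 and called without GY118F G-CSF replicate 3, camera adjusted p = 0.0383). Its call in control EpiSCs was lost with an estimated correlation (camera adjusted p = 0.0697). That test cannot decide, since the labels describe no unstimulated culture with the same handling, and a receptor-independent effect of G-CSF cannot be told apart from it. In control EpiSCs the real grouping called 4723 features and the highest of the other splits of the 6 arrays called 0, but 10 splits are too few for a share under 0.05, with 1 split as large.

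Features that rose more after G-CSF in GY118F EpiSCs could have recovered from a lower unstimulated level without exceeding stimulated control EpiSCs. Of the 432 features with a more upward change, 282 rose in GY118F EpiSCs, and 72.3% of these were called higher in stimulated GY118F than in stimulated control EpiSCs. That share decides nothing: a feature that starts level with control EpiSCs and rises more has to end above them, and the 2 contrasts share the stimulated arrays. Recovery was therefore weighed on the 118 of the 282 that were called lower in GY118F EpiSCs before G-CSF, of which 41 were called higher with G-CSF, 14 lower and 63 neither. Such features were also chosen on 1 stimulated GY118F array with 1 or 2 stimulated control arrays and tested on the other stimulated arrays, in 12 splits. On the held-out arrays 18.8% to 53.8% were called higher, and 57.4% to 84.6% lay above stimulated control EpiSCs with or without a call. The held-out GY118F arm is 1 array, and recovery stays open for these features, including Lefty1, Irf1 and Gbp2. Gbp2b and Cd40 were also called lower before G-CSF and were called higher than stimulated control EpiSCs with G-CSF, by 0.75 and 0.92.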

How the results depend on the processing

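No called named gene or gene list changed direction under any alternative run, while some values without a call changed sign. The other features were compared only as counts. Leaving out the dimmer 50 percent of features tests fewer features and called 1271 higher and 1481 lower in GY118F EpiSCs, 1448 and 1506 in control EpiSCs, 232 and 129 in the difference, 1110 and 1104 between unstimulated lines and 74 by the study's criterion, with 5 lists in control EpiSCs and 5 between unstimulated lines. A fold threshold of 1.4 left 468 and 472, 361 and 473, 197 and 81, and 351 and 379 in the same order, and a threshold of 0.01 left 220 and 100 in the difference. With an estimated correlation 3 lists were called in GY118F EpiSCs, 0 in control EpiSCs and 1 between unstimulated lines. The estimate was above the preset 0.01 for some lists, such as glycolysis and hypoxia (0.16), and below it for others. For WNT targets it was -0.047 and for the STAT3 list -0.016. A higher correlation of members thus does not account for the larger camera adjusted p of these lists, and the cause was otherwise not tested. A call lost with an estimated correlation is therefore not, by itself, evidence that the members of a list move together. Leaving out each array in turn, features more upward in GY118F EpiSCs ranged from 278 (without GY118F G-CSF replicate 2) to 496 (without GY118F unstimulated replicate 3) and more downward ones from 151 (without GY118F unstimulated replicate 2; 159 without control unstimulated replicate 2) to 352 (without GY118F unstimulated replicate 3); fewer arrays were fitted. Deviations of same-numbered unstimulated and stimulated arrays correlated at 0.26, 0.25 and -0.29 in control and -0.04 and 0.30 in GY118F EpiSCs (0.38 and 0.04 by the titles), and those of the stimulated lines at -0.01 and 0.54. Not every pair was over 0.1, so the numbers were not taken to pair the samples. That rule cannot show that the samples were unpaired. The deviations of the stimulated GY118F arrays mirror each other (0.30 and -0.30 with unstimulated replicate 3). Differently numbered arrays reached 0.50 (control unstimulated replicate 2 with control G-CSF replicate 3). With a replicate block by the numbers used here (source names for the stimulated GY118F arrays) 412 and 221 features were called in the difference, and by those of the titles 475 and 300. With the former the immediate early list in GY118F EpiSCs had an adjusted p of 0.0560. The Lefty1 difference between lines kept its call only without GY118F unstimulated replicate 3 or control G-CSF replicate 1 among the single arrays left out. Pou5f1 in control EpiSCs lost its call in 6 alternatives. Over the named genes, 19 calls were lost and 4 gained without single arrays, against 1253 values that stayed on their side of the threshold, and 9 were lost and 6 gained under other settings, against 987. A second quantile normalization moved values by at most 0.000105 and tests nothing. Background could not be tested without detection values.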

Other observations

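The test of sex chromosomes and the 2 tests of mixed RNA were chosen after the results were seen. In the oxidative phosphorylation list 2 of 17 members rose and 4 fell in GY118F EpiSCs and 3 rose and 4 fell in control EpiSCs, with mean changes of -0.03 and -0.02 and no call by camera (adjusted p = 0.523 and 0.538). The primed epiblast list had 6 of 15 members higher and 3 lower after G-CSF in GY118F EpiSCs, with Fgf15 at 0.67 and Otx2 at 0.48 against Dnmt3b at -0.37, and was not called (camera adjusted p = 0.522). Timp1, a secreted inhibitor of metalloproteinases, rose by 1.40 in GY118F and by 0.22 in control EpiSCs and Serpina3n by 0.28 in GY118F EpiSCs, the 2 measured members of the acute phase list, which was too small to test. Fibroblast markers (camera adjusted p = 0.160 and 0.452) and neural progenitor markers (0.304 and 0.0888) were not called after G-CSF in GY118F or control EpiSCs.

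Lefty1 and Nodal were higher in unstimulated GY118F replicate 3 than in replicates 1 and 2, by 3.39 and 1.26. RNA of unstimulated control EpiSCs in that sample would need a share of 26.3% from Lefty1 and predicts a median rise of 0.89 in 9 features that are low in GY118F EpiSCs in both states, but their median rise was 0.0044, which argues against it. RNA of stimulated GY118F EpiSCs would need 57.4% and predicts 0.88 in 15 features raised by G-CSF, against a median rise of 0.14. Higher Activin and Nodal pathway activity in that culture is a candidate explanation. The other 8 measured targets had a median difference of 0.23, above the 95th percentile of 10000 random lists matched on mean value. Tdgf1 and Fgf8 stood at 0.81, but Gsc (-0.17), Foxh1 (-0.16) and Id1 (-0.06) were lower. The random lists were not matched on the difference between the lines, and 8 of the 10 targets were lower in unstimulated GY118F EpiSCs. A general shift of that array toward control EpiSCs could thus pass this test too. The rise was not confined to these targets. Among the 15 largest deviations, looked up after their values were seen, Pde1b (0.91), Il17rd (0.90), Car2 (0.88) and Cd40 (0.87) rose as much in replicate 3. So did the mitochondrially encoded COX2 (0.87), ATP6 (0.84) and ND1 (0.82), while Rgcc (-0.78) and Btbd11 (-0.73) fell. All 5 features that deviated by over 1, Lefty1 and Nodal among them, moved toward unstimulated control EpiSCs. Car2 and Col2a1 (0.76) moved away from them. Replicate 3 also correlated more closely with the stimulated GY118F arrays (r = 0.981 with each) than replicate 1 (0.976 and 0.973) or replicate 2 (0.977 and 0.975) did. A broader difference of that culture or of its RNA was not tested, so pathway activity remains a hypothesis from 1 array.

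The 2 lines differed without G-CSF in 3723 features, against 0 in the highest of the other splits of the 6 arrays, and 10 splits, 1 of them as large, are too few for a share under 0.05. The lines may differ in sex chromosomes: Xist was lower in GY118F EpiSCs by 2.37 (-2.37), and in every array Eif2s3y and Kdm5d were higher there (8.71 to 9.17 against 7.13 to 7.24 for Eif2s3y). Xist ran the other way without overlap (7.15 to 7.22 in GY118F against 9.35 to 10.14 in control EpiSCs). The lines thus differed in the expression of these sex-linked genes. Uty, which the test also required, overlapped near the floor (7.42 to 7.57 against 7.29 to 7.51), where it can tell little. The test as set was therefore not met in full, and the chromosomes themselves were not examined. Ligand-independent STAT3 activity in GY118F EpiSCs could not be decided. The STAT3 list differed by a mean of 0.041, with Gadd45g (2.06) and Socs3 (0.73) called higher and 5 of the 15 members lower. That mean was under 10% of the list's 0.72 after G-CSF in GY118F EpiSCs, the bound set beforehand against such activity. A margin of 2 SE was then added, with which the bound was not met. The SE of 0.17 was taken over the members, so it measures the spread between genes and not between arrays.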
